A study of Mus musculus with 7 samples.

How the data were processed

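The samples were 7 mouse RNA samples, each on an Affymetrix murine transcriptome array (MTA 1.0): 4 of cultured induced neurons (in vitro) and 3 of laser-captured skin enriched for induced neurons (in vivo). Per the labels' protocols, RNA was extracted with a PicoPure kit, fragmented and labelled with biotin. Groups and replicate numbers came from the sample titles, and the columns of the value table were matched to samples by their identifiers. There were 0 columns of other samples.

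The values are log2 signals as deposited, with a value for each transcript cluster and array. Per the submitters' processing notes they were made with Affymetrix Expression Console. Its version, the summary algorithm, the normalization between arrays, the filters and the genome build were not given in the sources used here. The log base was taken as 2 because that program writes log2 signals, so every fold printed rests on this base. The values ran from -6.23 to 5.38 with 0 missing. In every cluster between 1 and 6 of the 7 values were below 0, and in 22.7% of clusters a pair of arrays was symmetric about 0 within 2e-06, which is what subtracting a median over an even number of arrays, with some that are not among these 7, would leave. The table therefore holds differences between arrays and no expression levels, and which arrays set the zero is unknown. Each difference between groups is unaffected by a value subtracted per cluster. The direction follows from the column of each array. The column medians were -0.0182, -0.017, -0.0208 and 0.0178 for in vitro replicates 1 to 4, and 0.215, 0.189 and 0.207 for in vivo replicates 1 to 3.

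Of the 65770 clusters, 30473 had 1 gene symbol in the platform annotation, 2176 had several and 33121 had none there. Only clusters with 1 symbol were named. They held 30137 symbols, of which 29810 (98.9%) were found in a RefSeq gene table of assembly GRCm38.p6 that was used for names only. Of the symbols, 251 had several clusters. A named gene or list member with several clusters counted as passing only if all its clusters passed in the same direction, with the mean difference and the largest SE and p. No coordinates are printed, because the sources used here name no build for the array annotation. Ascl1 had no cluster with a single symbol and was not analysed here.

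All tests were run in R 4.3.3 with limma 3.58.1. The main fit used lmFit and eBayes on the values as deposited, with group as the only term, all 65770 clusters, Benjamini-Hochberg adjustment and a threshold of 0.05. A second count required an absolute log2 difference of at least 1. Limma's treat tested for differences beyond 1, and clusters whose 95% confidence interval lay within -1 to 1 were counted as alike. Gene lists, 37 in all, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. List members were also adjusted over the list alone. List means and the likeness of arrays were tested exactly over the 35 groupings of the arrays.

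The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The rule named, among clusters with 1 symbol, passing the threshold and with no overlap between the groups, the 12 genes with the largest difference in each direction, leaving out predicted genes, microRNAs, small nucleolar RNAs and olfactory and vomeronasal receptors. It also named the delivered factors and up to 4 members of each list that passed with the largest differences. Added after the data were examined were a scaling to olfactory, vomeronasal and bitter taste receptor clusters (1421 clusters), the median absolute difference between arrays, a list test with the first cluster of each gene, and lists of developmental muscle, secretory pathway, mitochondrially encoded and organ genes.

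Some planned choices need an expression level, which centred values do not hold: a filter on dim clusters, quantile normalization, and picking the cluster with the highest mean to stand for a gene. They were not used. For list tests the clusters of a gene were averaged instead. A pseudocount was not needed on a log scale. Alternatives that were run are median-centred and receptor-centred arrays, a trended and robust variance, array weights with a variance for each group, the replicate number as a block, only clusters with 1 symbol, the other list tests, and leaving out each array in turn.

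The fit was tested on simulated data with the 65770 clusters and 200 changed ones. With the spread of each group as measured, 81% of changes of 1 and 93% of changes of 2 on the log2 scale were recovered, and 83 of the unchanged clusters were called, 32.3% of all calls. With a shared spread 77% and 94% were recovered and 16 were called, 8.56% of calls. The median SD within a group was 0.0826 in vitro and 0.132 in vivo, so false calls may exceed the nominal share. In the same simulation a list raised by 1 passed camera and 0 other lists did. Its noise was drawn independently for each cluster, so it cannot show the false list calls that camera may give where genes are correlated. The simulated shares of false calls rest on 200 changed clusters and do not carry over to the real counts.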

Results

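The series set cultured induced neurons against induced neurons made in living skin. Induced neurons are cells converted directly from another cell type, here fibroblasts or cells of the skin, by forced expression of the neurogenic transcription factors Ascl1, Brn2 (gene symbol Pou3f2) and Myt1l. The in vitro group held 4 arrays of mouse fibroblast cultures that had received the factors by electroporation without a virus. The in vivo group held 3 arrays of tissue pieces, enriched for induced neurons, that were cut by laser from mouse skin transfected with the same factors. Total RNA of each sample was read on an Affymetrix MTA 1.0 array, which measures whole transcripts in groups of probes called transcript clusters. All 65770 transcript clusters had a value on each of the 7 arrays. The title of the series asks how alike the expression profiles of the 2 kinds of induced neuron are. All differences below are in vivo minus in vitro on a log2 scale, with the standard error (SE) from a limma fit to 3 in vivo and 4 in vitro arrays, and adjusted p-values are Benjamini-Hochberg values from that fit. The labels do not say whether the arrays came from separate cultures or separate mice, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. No array repeated another: the closest pair, in vitro replicates 1 and 3, had a median absolute log2 difference of 0.0461.

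The largest increases in vivo were in genes of the contractile apparatus of skeletal muscle and of the outer layers of the epidermis. Fibroblast markers and matrix remodelling enzymes were lower in vivo than in the cultured cells. Tnnc2, the calcium-binding troponin of fast muscle fibres, was 32.8-fold higher in vivo (log2 difference 5.03 ± 0.13 SE, adjusted p = 2.96e-06). Fat4, a very large cadherin of the cell surface, was 35.8-fold higher in vitro (log2 difference -5.16 ± 0.099 SE, adjusted p = 1.32e-06). The genes named for the largest differences, 12 in each direction, were chosen among those whose arrays did not overlap between the groups.

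Of the 12 named genes with the largest increase in vivo, 9 belong to skeletal muscle. Besides Tnnc2 they were Tnnt3, the troponin T of fast fibres (4.86 ± 0.21, adjusted p = 1.52e-05), Atp2a1, the calcium pump of the sarcoplasmic reticulum (4.66 ± 0.26), the fast myosin heavy chains Myh1 (4.43 ± 0.38) and Myh4 (4.28 ± 0.20), the giant filament protein Ttn (4.10 ± 0.48), Tcap, which caps it at the Z-disc (3.46 ± 0.18), the muscle creatine kinase Ckm (3.42 ± 0.24) and Neb, which runs along the thin filament (3.41 ± 0.33). The other genes were Krt10, a keratin of the upper epidermis (3.75 ± 0.41, 13.5-fold, adjusted p = 0.00038), Flg2, a protein of the cornified layer (3.38 ± 0.38), and the hair keratin-associated gene Krtap22-2 (3.42 ± 0.27). Myosin heavy chain genes and keratin-associated genes have close copies whose transcripts probes may share, so the values of Myh1, Myh4 and Krtap22-2 are uncertain as to the copy.

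**Figure D1:**
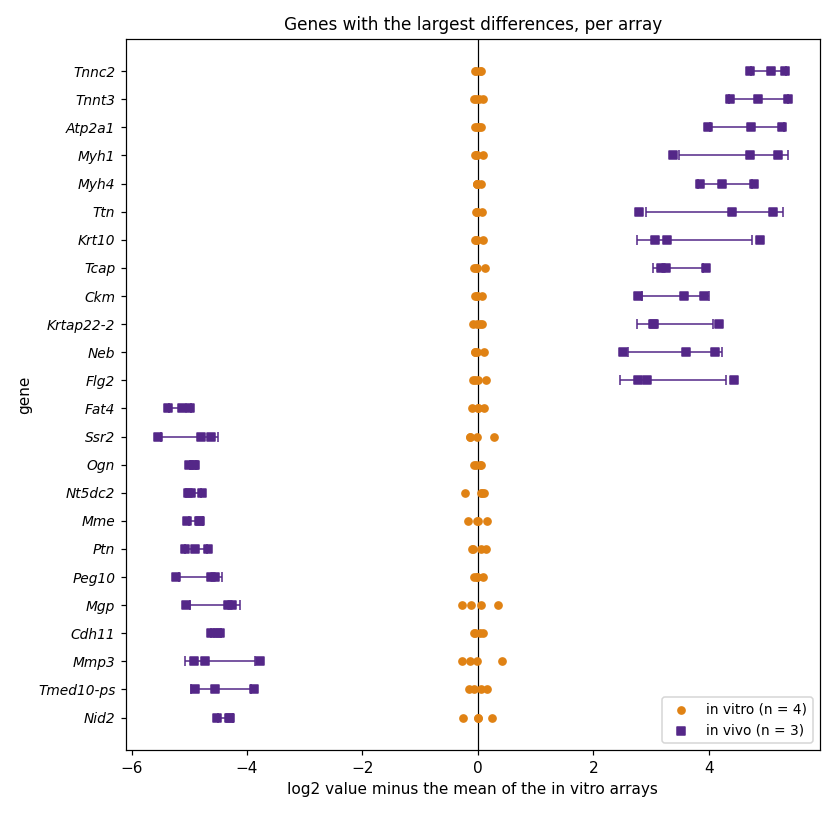
Log2 difference from the in vitro mean (horizontal axis) of the 24 named genes with the largest differences, with a circle for each of the 4 in vitro arrays, a square for each of the 3 in vivo arrays and an error bar giving the SD of the in vivo arrays. By the mean of the in vivo arrays, Tnnc2 and other muscle genes lie farthest to the right and Fat4 farthest to the left. Genes were chosen among those with no overlap between the groups.

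All 18 measured skeletal muscle markers were higher in vivo, with a median log2 difference of 2.95. Each of them stayed higher after centring each array on its median cluster and without in vitro replicate 4. The camera test of the list gave an adjusted p of 7.41e-07, and with an estimated correlation between genes the adjusted p was 0.433. With an estimated correlation 0 of the 37 lists passed, so a miss there does not separate strong lists from weak ones. All 7 measured myogenic regulators were higher as well, at a smaller median of 0.52, and 5 stayed higher after median centring and 4 after centring on clusters of olfactory and other sensory receptors (receptor centring). Myf5 turned from 0.16 to -0.053 and -0.085 with these scalings. They included Myf6, a regulator of late muscle differentiation (1.22 ± 0.24), Myog, which drives fusion into fibres (0.79 ± 0.14), Pax7 of muscle stem cells (0.62 ± 0.068) and Myod1 (0.52 ± 0.057). Their camera adjusted p was 0.0391, and it was 0.433 with an estimated correlation and 0.0654 without in vitro replicate 4.

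Epidermal genes were higher in vivo too. Of 20 suprabasal keratinocyte markers, 18 were higher, 1 was lower and 1 did not pass, and the median was 1.71. Adjusted over the list alone, 19 were higher and 1 was lower, and after centring 16 and 1. The in vivo arrays were uneven: the list mean was 2.31 on in vivo replicate 2 against 1.20 and 1.35 on replicates 1 and 3, and Krt10 was 4.85 against 3.02 and 3.24. The mean of the sebaceous and skin lipid list was likewise 1.12 against 0.48 and 0.55. The muscle list mean was 2.83 on in vivo replicate 2 against 3.11 and 3.56 on replicates 1 and 3. Single muscle genes varied: Ttn was 2.78 against 4.39 and 5.09, and Tnnc2 was 5.06 against 4.70 and 5.30. Dmkn, a secreted protein of the upper epidermis (2.79 ± 0.42), and Asprv1, a protease that processes filaggrin (2.57 ± 0.25), followed Krt10 and Flg2. Of 17 basal keratinocyte markers, 15 were higher and 1 was lower (13 and 1 after centring), with a median of 0.81. Krt5 (3.33 ± 0.30) and Krt14 (1.41 ± 0.087), the keratin pair of the basal layer, the desmosome protein Dsp (2.24 ± 0.35) and the desmosome-associated Perp (1.38 ± 0.23) were the largest of them by rule. Both lists had a camera adjusted p of 0.00193, and with an estimated correlation the adjusted p was 0.477 for suprabasal and 0.433 for basal markers.

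A large part of the array lay higher on the in vivo arrays, and gene groups have to be read against it. The median cluster differed by 0.23 and the array medians differed by 0.21. Clusters of olfactory, vomeronasal and bitter taste receptors, which skin and fibroblasts hardly use, had a median of 0.25. Of 38 measured genes of organs outside skin, such as liver, pancreas, retina and testis, 33 were higher in vivo and none was lower, with a median of 0.44. The receptor and organ genes were chosen after the data were examined. For each list below, the counts after centring each array on its median cluster stand beside the counts on the values as deposited.

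Markers of other skin components were higher in vivo by amounts mostly close to that of the organ genes. The list medians were 0.41 for the hair follicle (15 of 17 higher), 0.83 for the sebaceous gland (10 of 12 higher, 1 lower), 0.41 for melanocytes (8 of 9), 0.63 for adipocytes (8 of 12, 1 lower), 0.50 for endothelium (13 of 14, 1 lower), 0.62 for mural cells (8 of 10), 0.49 for Schwann cells (8 of 9, 1 lower) and 0.49 for red blood cells (2 of 2, with 8 of the 10 listed genes not measured as a gene of their own). Median centring left 8 hair follicle (5 with receptor centring), 7 sebaceous, 4 melanocyte, 6 adipocyte, 12 endothelial, 8 mural, 6 Schwann cell and 2 red blood cell genes higher. Among single members, Car3, an abundant carbonic anhydrase of fat and muscle, differed by 2.66 ± 0.31, the muscle and mural filament protein Des by 1.67 ± 0.13, the hair follicle keratins Krt17 and Krt75 by 1.43 ± 0.10 and 1.14 ± 0.095, the lipid desaturase Scd3 by 1.43 ± 0.22, the pericyte gene Rgs5 by 1.14 ± 0.064, the endothelial cadherin Cdh5 by 1.07 ± 0.084, the melanosome protein Mlana by 0.75 ± 0.12, the myelin protein Mbp by 0.63 ± 0.094 and the erythroid band 3 gene Slc4a1 by 0.54 ± 0.068. Cd36, the fatty acid transporter, went the other way (-1.42 ± 0.31), as did the endothelial factor Erg (-1.60 ± 0.12) and the myelin gene Pmp22 (-0.73 ± 0.12). The camera adjusted p was 0.00379 for hair follicle, 0.00438 for endothelium, 0.0185 for mural cells and 0.0399 for melanocytes, and with an estimated correlation the adjusted p was 0.444, 0.433, 0.433 and 0.433. Sebaceous, adipocyte, Schwann and red blood cell lists did not pass (adjusted p = 0.063, 0.0663, 0.0659 and 0.15), and without in vitro replicate 4 melanocytes did not either (0.0531). After median centring the sebaceous (0.00577), adipocyte (0.0144) and Schwann (0.0207) lists passed, as they did after receptor centring (0.00284, 0.0119 and 0.0193). The sebaceous list also passed with array weights (0.0384), without in vivo replicate 1 (0.0355) and without in vivo replicate 2 (0.0148), and the adipocyte list without in vivo replicate 1 (0.0465). With an estimated correlation, on the values as deposited, the adjusted p of these 3 lists was 0.461, 0.461 and 0.433.

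Immune lists were split. Of 13 granulocyte and mast cell markers, 12 were higher in vivo (13 adjusted over the list alone, 7 after centring), with a median of 0.47, led by the mast cell proteases Mcpt4 (1.17 ± 0.22) and Tpsb2 (0.78 ± 0.13). Of 12 lymphocyte markers, 11 were higher and 1 was lower (9 and 1 after centring), with a median of 0.53; the B cell receptor parts Cd79a (0.77 ± 0.095) and Cd79b (0.64 ± 0.096) were higher and the interleukin 7 receptor Il7r was lower (-0.82 ± 0.22), a call lost with array weights (adjusted p = 0.0505). The camera adjusted p was 0.0143 and 0.0348, and 0.433 for both with an estimated correlation; the lymphocyte value was 0.0502 without in vitro replicate 4. Of 17 macrophage and dendritic cell markers, 5 were higher, 4 were lower and 8 did not pass (camera adjusted p = 0.583). After centring 4 were higher and 5 lower. H2-Ab1, a class II antigen-presenting chain, was higher (2.08 ± 0.18), while the lysosomal Cd68 (-2.39 ± 0.27), the lysozyme Lyz2 (-2.04 ± 0.26) and the signalling adaptor Tyrobp (-1.75 ± 0.34) were lower. Of 18 inflammatory cytokines and chemokines, 9 were higher and 2 were lower (4 and 3 after centring, adjusted p = 0.308), with the monocyte chemokine Ccl8 differing most (2.64 ± 0.28).

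Fibroblast genes were lower in vivo than in the cultures. Of the 12 named genes with the largest decrease, Ogn, a small proteoglycan of the matrix (-4.94 ± 0.057), Mgp, an inhibitor of matrix calcification (-4.55 ± 0.22), Nid2 of the basement membrane (-4.37 ± 0.12), Cdh11, the cadherin of mesenchymal cells (-4.53 ± 0.066), the matrix metalloproteinase Mmp3 (-4.47 ± 0.29), the membrane endopeptidase Mme (-4.89 ± 0.094) and the secreted growth factor Ptn (-4.88 ± 0.11) act in or at the matrix and cell surface. The others besides Fat4 were Ssr2, a part of the translocon complex of the endoplasmic reticulum (-4.99 ± 0.22), Nt5dc2 (-4.93 ± 0.10), the imprinted gene Peg10 (-4.80 ± 0.16) and Tmed10-ps (-4.45 ± 0.22), a pseudogene that probes may not separate from its parent gene.

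Of 26 fibroblast markers, 20 were lower in vivo, 2 were higher and 4 did not pass, with a median of -1.21. Fibronectin (Fn1, -4.33 ± 0.26), the mesenchymal transcription factor Snai2 (-4.24 ± 0.15), the growth factor receptor Pdgfrb (-2.88 ± 0.13) and the collagen crosslinking enzyme Loxl1 (-2.83 ± 0.17) differed most. Of 17 matrix remodelling enzymes, 14 were lower and 1 was higher, with a median of -1.39, including Mmp14 (-3.53 ± 0.32), Mmp2 (-3.21 ± 0.40) and Mmp12 (-3.14 ± 0.20). Centring gave 21 lower fibroblast markers and 16 lower remodelling enzymes. The camera adjusted p was 7.41e-07 and 4.02e-06, and 0.433 for both with an estimated correlation. The contractile and matricellular genes of cultured fibroblasts went both ways (6 higher, 6 lower and 3 not passing of 15, 3 higher and 6 lower after centring, adjusted p = 0.132). Among them the focal adhesion protein Vcl (-3.21 after centring), the matricellular Thbs1 (-2.66 ± 0.16) and Ccn1 (-2.34 ± 0.20), and Cnn2 (-2.26 ± 0.13) were lower. Tpm2, a tropomyosin (1.65 ± 0.13), and the matricellular Ccn2 (0.64 ± 0.083), picked after their values were seen, were higher under both scalings.

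Neuronal genes were not uniformly higher or lower in either group. Of 22 pan-neuronal genes, 15 were higher in vivo, 2 were lower and 5 did not pass, and the median was 0.41, near that of the genes of organs outside skin. After median centring the counts were 8 higher and 4 lower, and after receptor centring 5 and 2. The list mean was 0.302 on in vivo replicate 2, which also had the highest keratinocyte means, against 0.121 and 0.0282 on in vivo replicates 1 and 3. Relative to other genes the mean difference was 0.14 with all arrays and 0.077 without in vivo replicate 2. Nsg1, an endosomal protein of neurons (-3.02 ± 0.14), and the adhesion molecule Ncam1 (-1.37 ± 0.14) were lower in vivo, and Stmn3 (0.67 ± 0.093) and the RNA-binding Elavl3 (0.58 ± 0.14) were higher, although Elavl3 did not pass after centring. The neuronal tubulin Tubb3 (-0.06 ± 0.092, adjusted p = 0.581) and the dendritic protein Map2 (0.0065 ± 0.062, adjusted p = 0.927) did not pass, and were picked after their values were seen. Median centring put Map2 at -0.21 and past the threshold (adjusted p = 0.0447), and receptor centring put it at -0.24 and not past it (0.0546). The camera adjusted p was 0.133 (0.0468 after median centring), and with an estimated correlation the adjusted p was 0.534.

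Of 20 neurogenic transcription factors, 15 were higher and 4 were lower in vivo, and centring turned this to 3 higher and 4 lower. The list's median was 0.30, its mean was -0.06, and it did not pass camera, which compares a list with other genes (upward direction, adjusted p = 0.344). The 4 members lower under both scalings were Sox4 (-3.32 ± 0.12), Pou3f4 (-1.84 ± 0.19), Ebf3 (-1.26 ± 0.12) and Ebf1 (-0.94 ± 0.10), all factors of neural development that other tissues also use. Of 14 neurotransmitter identity genes, 14 were higher (10 after median and 5 after receptor centring), with a median of 0.44. They included the glutamate transporter Slc17a7 (0.76 ± 0.090) and the dopamine and serotonin transporters Slc6a3 (0.58 ± 0.069) and Slc6a4 (0.56 ± 0.063). Of 10 sensory neuron markers, 10 were higher (3 after median and 2 after receptor centring), with a median of 0.43. Isl1 had the largest difference (0.66 ± 0.16) and did not pass after median (adjusted p = 0.0507) or receptor centring (0.0679). These lists had camera adjusted p of 0.00379 and 0.0215, and 0.461 for both with an estimated correlation.

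Synaptic and channel genes had medians near that of the pan-neuronal list and did not pass camera on the values as deposited. Of 17 presynaptic genes, 13 were higher and 1 was lower (4 and 1 after median centring, 2 and 1 after receptor centring, median 0.37, adjusted p = 0.063), and the list mean was 0.578 on in vivo replicate 2 against 0.263 and 0.209 on replicates 1 and 3. Of 16 neurotransmitter receptor and postsynaptic genes, 12 were higher and 2 were lower (8 and 2 after median centring, 5 and 2 after receptor centring, median 0.34, adjusted p = 0.0663). Of 15 voltage-gated channels, 12 were higher and 2 were lower (4 and 2 after centring, median 0.35, adjusted p = 0.0663). The vesicle fusion protein Snap25 (0.97 ± 0.35) and the kinase Camk2a (1.03 ± 0.095) were higher, and the glutamate receptor Gria3 (-1.89 ± 0.13), the calcium channel subunit Cacna2d1 (-0.97 ± 0.17) and the vesicle protein Vamp2 (-0.73 ± 0.12) were lower. After median centring, camera passed the presynaptic list (adjusted p = 0.0315) and the channels (0.0468), and after receptor centring only the former (0.0383). The presynaptic list also passed with array weights (0.0481), without in vivo replicate 1 (0.0419) and without in vivo replicate 3 (0.0309). With an estimated correlation, on the values as deposited, the adjusted p was 0.534 for the presynaptic list, 0.461 for the postsynaptic list and 0.433 for the channels. The Snap25 call was lost when any of the 4 in vitro replicates was left out (0.95 to 1.02, adjusted p = 0.0536 to 0.082) and after median (0.76, adjusted p = 0.123) or receptor centring (0.73, adjusted p = 0.131), and its difference was 0.49 without in vivo replicate 2. Of 14 neural progenitor and glial markers, 10 were higher and 1 was lower (7 and 1 after centring, median 0.42, adjusted p = 0.0659), with Olig1 at 0.93 ± 0.11 and Sox9 at -1.93 ± 0.12. That list passed camera after median centring (0.0315), after receptor centring (0.0383) and without in vivo replicate 3 (0.0409), and its adjusted p was 0.457 with an estimated correlation. Of 20 axon guidance genes, 6 were higher and 8 were lower (4 and 10 after centring, median -0.11, adjusted p = 0.0663); Efnb2 (-2.24 ± 0.13), Plxna2 (-1.71 ± 0.17) and Robo2 (-1.63 ± 0.073) were lower. The axon guidance list passed as lower without in vivo replicate 2 (adjusted p = 0.046), and its adjusted p was 0.461 with an estimated correlation. Of 12 neurotrophic factors and receptors, 8 were higher and 3 were lower (4 and 3 after centring, median 0.33, mean -0.07, adjusted p = 0.598), and the GDNF receptor Gfra1 was lower by far the most (-2.73 ± 0.11).

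Of the 3 delivered factors, 2 had a transcript cluster of their own. Pou3f2 differed by 0.18 ± 0.059 (adjusted p = 0.0282), and by -0.03 after centring (adjusted p = 0.697). Its call was also lost with array weights (adjusted p = 0.0605), without in vitro replicate 1, 2 or 3 (0.0763, 0.0793 and 0.0784) and without in vivo replicate 2 (0.0664). Myt1l differed by 0.0025 ± 0.074 (adjusted p = 0.977), and by -0.21 after centring (adjusted p = 0.0402). Probes may read the endogenous transcript, the delivered one or both. Ascl1 was not analysed here.

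Many nuclear genes of respiration, translation and sterol synthesis were lower in vivo. The cause of these decreases was not tested. Tissue and preparation changed together with group, and most receptor and organ genes were higher on the same arrays. A technical cause is therefore not excluded, and the decreases do not show lower respiration or translation in the cells. Of 22 oxidative phosphorylation genes encoded in the nucleus, 14 were lower, none was higher and 8 did not pass, with a median of -0.98. The complex I subunit Ndufa9 (-2.35 ± 0.26) and the complex III subunit Uqcrc1 (-2.08 ± 0.23) differed most. The 5 measured respiratory genes encoded in mitochondria, a list written after the main differences were seen, were all higher in vivo, from 0.64 for COX2 to 3.31 for ND6. Of 15 measured ribosomal protein genes, 13 were lower (14 adjusted over the list alone), with a median of -1.16, including Rpl4 (-2.21 ± 0.24) and Rpl8 (-2.17 ± 0.24); ribosomal protein genes have many processed pseudogenes, so single values are uncertain. Of 15 cholesterol synthesis genes, 9 were lower and none was higher, with a median of -0.44, including Sc5d (-1.20 ± 0.12) and Fdps (-0.97 ± 0.15). Of 15 glycolysis genes, 8 were lower and 3 were higher, with a median of -0.23. Pgam1 (-2.28 ± 0.15) and Pkm (-1.60 ± 0.19) were lower, and the muscle phosphofructokinase Pfkm was higher (1.18 ± 0.23). In vivo replicate 2 lay closest to the in vitro arrays, with a list mean of -0.39 against -1.21 and -0.85 on in vivo replicates 1 and 3 for oxidative phosphorylation, and of -0.52 against -1.10 and -0.98 for ribosomal proteins. Centring gave 15, 14, 13 and 10 lower genes in these lists. The camera adjusted p was 3.36e-05, 1.14e-05, 0.00144 and 0.0203, and with an estimated correlation the adjusted p was 0.461, 0.457, 0.457 and 0.461. The glycolysis call was lost with receptor centring (adjusted p = 0.0577).

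Of 19 interferon response genes, 11 were lower in vivo, 1 was higher and 7 did not pass (13 lower and 1 higher after centring), with a median of -0.35 and a camera adjusted p of 0.00193. With an estimated correlation the adjusted p was 0.461. The antiviral membrane protein Bst2 (-3.38 ± 0.083), the RNA sensor Ddx58 (-2.24 ± 0.084), Ifit1 (-2.22 ± 0.22) and the transcription factor Stat2 (-1.82 ± 0.11) differed most. Cell cycle genes went both ways (8 higher and 7 lower of 22, 2 and 10 after centring, median 0.08, mean -0.15, adjusted p = 0.56), and the replication genes Pcna (-1.77 ± 0.22), Mcm6 (-1.23 ± 0.17) and Mcm4 (-1.05 ± 0.10) were lower. Of 16 immediate early and stress genes, 4 were higher and 4 were lower (2 and 4 after centring, median 0.06, mean -0.17, adjusted p = 0.583), with Jun lower by the most (-2.30 ± 0.14).

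**Figure D2:**
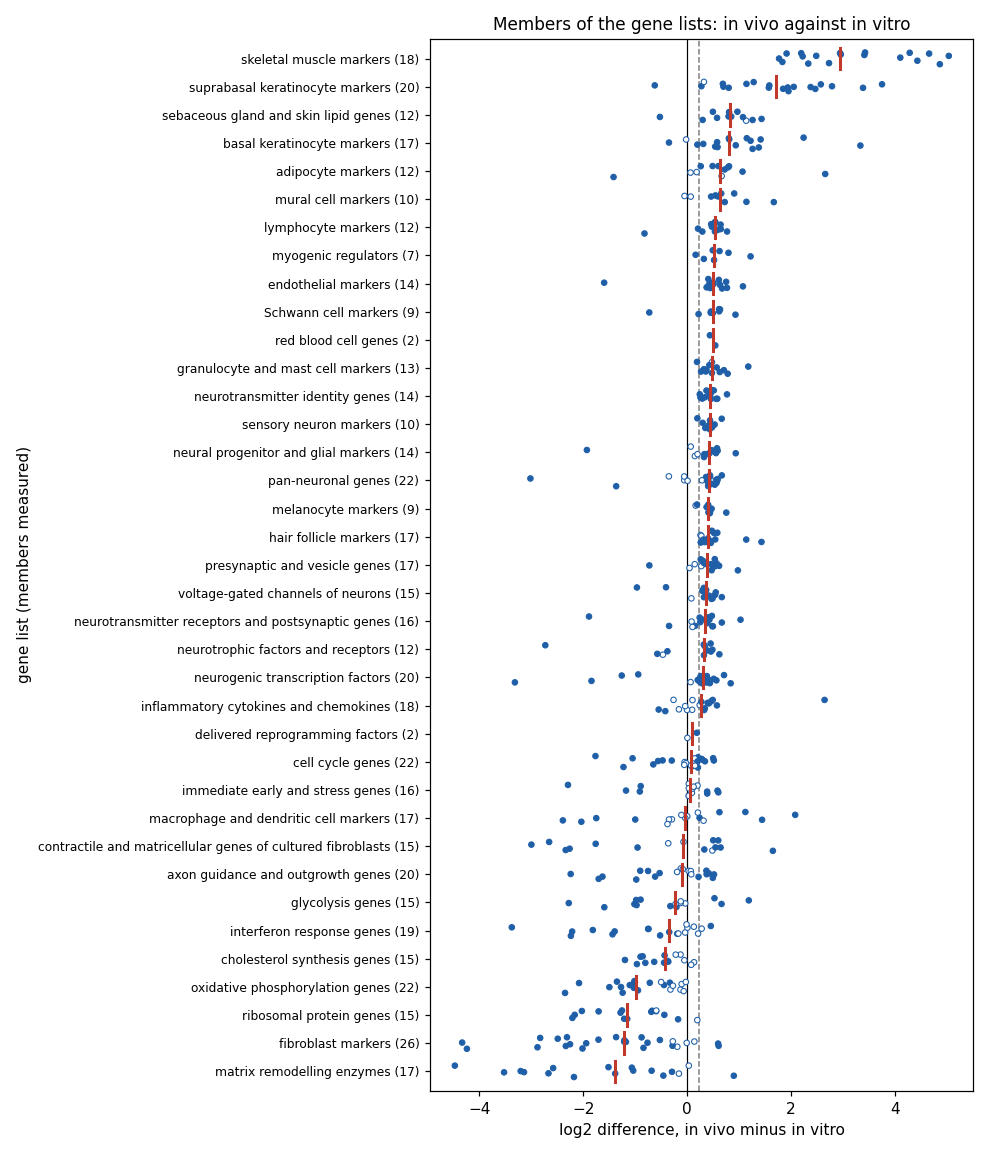
Log2 difference, in vivo minus in vitro (horizontal axis), of each measured member of the fixed gene lists, filled where the adjusted p was under 0.05 and open where it was not, with a red bar at each list's median. Skeletal muscle markers (median 2.95) stand to the right of the dashed line at the median of all clusters (0.23), and fibroblast markers (-1.21) and matrix remodelling enzymes (-1.39) to its left.

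All camera calls of lists rested on the preset correlation. Of the 37 fixed lists, 19 passed camera with a preset correlation of 0.01 (12 higher and 7 lower) and 0 passed with the correlation estimated from the arrays, where the smallest adjusted p was 0.433; 33 passed fry, which does not compare a list with other genes. The muscle list, with all 18 measured members higher, was among those that missed with an estimated correlation. A miss with that setting therefore does not show that a list was unchanged. In an exact permutation test of the absolute difference in list means over the 35 groupings of the arrays, 31 lists reached 0.0286, the smallest p those groupings can give. Except where a second count is given, adjusting over the list alone gave the same number of members higher and lower, apart from 17 rather than 15 hair follicle and 9 rather than 8 cell cycle genes higher.

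Across the whole array, the share of transcript clusters that differed between the captured skin pieces and the cultures depended on the scaling. It was 67.5% on the values as deposited, 42.5% after median centring and 39.4% after receptor centring. Among clusters that differed at least 2-fold, more were higher in vitro than in vivo under each of these scalings. Tissue and preparation changed together with group, and no array of skin or fibroblasts without the factors was among the samples. The counts therefore compare captured skin with cultures and do not give the difference between induced neurons alone. Limma called 44422 of 65770 clusters (67.5%) at an adjusted p under 0.05, 34319 of them higher in vivo and 10103 higher in vitro. At least 2-fold differences were found in 6651 clusters, 2422 higher in vivo and 4229 higher in vitro. Among clusters with a single gene symbol these were 775 and 3433. Differences shown to exceed 2-fold by the treat test were found in 1943 clusters, with 2714 without in vitro replicate 4 and 1271 without in vivo replicate 1. On the values as deposited, which include the shift between the array medians, the ranges of the groups did not overlap in 68.6% of clusters, against 5.71% by chance. This share was not computed after centring. The share of calls higher in vivo was 77.3% on the values as deposited, 47.7% of 27956 calls with each array centred on its median, and 43.8% of 25930 calls with each array centred on its receptor clusters, a scaling chosen after the data were examined. Of the clusters that differed at least 2-fold, the share higher in vivo was 36.4%, 19.7% and 17.9%.

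Likeness was counted from intervals. In 52264 clusters (79.5%) the 95% confidence interval of the difference lay within 2-fold in either direction. In 11563 clusters the data showed neither a difference beyond 2-fold nor likeness within it. The values hold no expression level, so clusters near background in both groups count as alike, and the number does not say how many expressed genes were alike.

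Whole profiles lay closer within the groups than between them. The median absolute log2 difference between arrays averaged 0.0913 within the in vitro group, 0.15 within the in vivo group and 0.353 between groups. In an exact one-sided permutation test over the 35 groupings p was 0.0286, the smallest they can give; this measure was added after the data were examined because the values are centred within each cluster. In vitro replicate 4 lay 0.115 to 0.132 from the other in vitro arrays and 0.258 to 0.301 from the in vivo arrays, while in vitro replicates 1 to 3 lay 0.0461 to 0.063 from each other. The Pearson correlation across clusters, chosen before the data were examined, averaged 0.184 within the in vitro group, 0.886 within the in vivo group and -0.289 between groups. Its difference within minus between was 0.707, and the exact one-sided permutation p was 0.0571, since setting in vitro replicates 1 to 3 against the other 4 arrays gave a difference at least as large. Without in vitro replicate 4 the difference was 1.28, with p = 0.1 in the exact permutation test, the smallest that 3 against 3 arrays can give. In vitro replicate 4 correlated at -0.547 to -0.142 with the other in vitro arrays and at 0.307 to 0.42 with the in vivo arrays. Clusters are not independent replicates, and centring within each cluster pushes correlations between dissimilar arrays below 0. The first principal component held 82.8% of the variance and separated the groups.

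**Figure D3:**
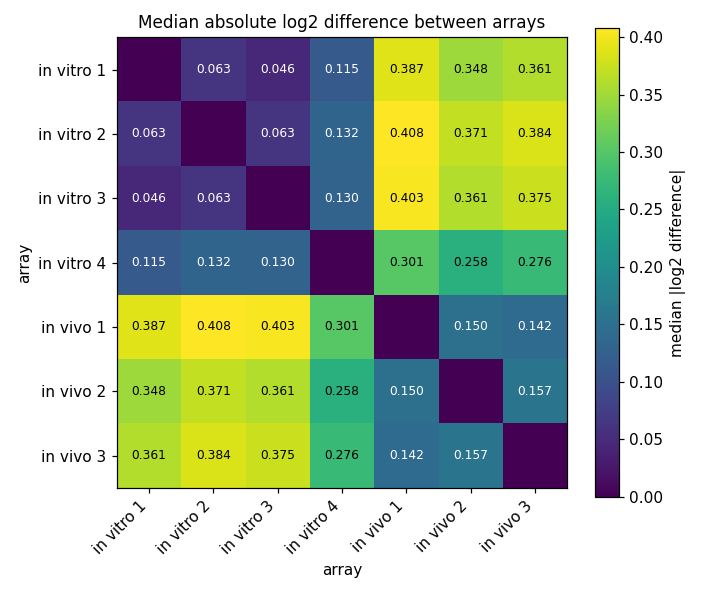
Median absolute log2 difference over all transcript clusters for each pair of the 7 arrays. The 3 in vivo arrays lie 0.142 to 0.157 apart, and pairs across the groups lie 0.258 to 0.408 apart, with in vitro replicate 4 nearest to the in vivo arrays.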

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

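The list tests of in vitro replicate 4 below were chosen after its position was seen. Every value that stood apart by Dixon's criterion belonged to in vitro replicate 4. Of 66 values tested in the 4 in vitro arrays, 8 had a gap to the nearest array, as a share of the group's range, above Dixon's 95% critical value for 4 samples, where chance gives about 1 in 20, or 3.3. That share was 0.9026 for the array median, 0.8378 for Myh1, 0.9505 for Myh4, 0.8401 for Nt5dc2, 0.93 for Myt1l, 0.9104 for the mean of the suprabasal keratinocyte list, 0.8484 for the endothelial list and 0.8401 for the granulocyte and mast cell list. Replicate 4 was higher than the other in vitro arrays in each except Nt5dc2 (0.93 against a mean of 1.23). The differences were small in size, such as 0.22 against 0.02 for Myt1l and 0.09 against -0.06 for the suprabasal list.

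In vitro replicate 4 also lay nearer to the in vivo arrays than the other in vitro arrays did. Its differences from in vitro replicates 1 to 3 followed those of the in vivo mean with a slope of 0.275 across clusters, part of which comes from the shared baseline. Skin or muscle RNA in this sample is argued against: the 38 muscle and suprabasal genes lay 0.10 above in vitro replicates 1 to 3, inside the range of random receptor lists (0.0833 to 0.203), while the same genes differed by 2.28 in vivo. A general rise of dim clusters on this array stays open, since 94.1% of receptor genes were higher in it than in the other in vitro arrays. Its fibroblast (-0.22), matrix remodelling (-0.26) and cholesterol (-0.22) genes had median differences below 0 against replicates 1 to 3. The design gives no biological difference between the in vitro arrays, and no biological explanation was tested.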

How the results depend on the processing

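The receptor centring, the median absolute difference and the first cluster of a gene were chosen after seeing the data. With arrays centred on their medians 27956 clusters passed, 13343 higher in vivo, 1360 of them at least 2-fold, and 19 lists were higher; with receptor centring these were 25930, 11356 and 1264, with 17 lists higher. The changed cluster counts follow from the shift that each scaling removes. List differences relative to other genes stayed the same, such as 0.37 for the presynaptic list, and why more lists passed was not tested. Pou3f2 turned to -0.029 and -0.061 and Myt1l to -0.21 and -0.24. Of the 44422 clusters, 23446 kept their call and direction after median centring. Only clusters with 1 symbol, fewer being tested, gave 22395 calls, 14567 higher in vivo, 4212 at least 2-fold, 777 of these higher in vivo, and 23042 alike. Camera with an estimated correlation passed 0 lists (0 higher, 0 lower), and fry 33 (22 higher, 11 lower). The likeness of arrays passed by median absolute difference (0.242); for other measures the cause was not tested. Leaving out each array gave 35405 to 46601 calls, 1271 to 2714 clusters beyond 2-fold (lowest without in vivo replicate 1, the cause was not tested) and -0.037 to 0.052 for Myt1l. The other counts stayed within 1.5 times the main count.

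No pairing of the arrays by replicate number was seen: residual correlations were -0.01, -0.10 and 0.09, and 1 of 3 in vitro arrays correlated best with its own number. With so few pairs the check has little power, so pairing is not excluded. With the replicate block 42045 clusters passed, 39093 of them shared with the main calls, and the melanocyte and myogenic lists lost theirs. Of 161 genes named by rule, 151 kept their call in every setting; Elavl3, Snap25, Isl1, Mrgprd, Dct, Cplx1, Retn, Il7r, Pou3f2 and Myt1l did not. Not run were quantile normalization, the dim filter and the highest mean cluster, because values are centred, and a pseudocount, because they are on a log scale. Centred values hold no signal over background, so what dim clusters limit is unknown.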

Other observations

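The tests in this part used gene lists that were written after the main differences were seen, except the skeletal muscle, neuronal and respiratory chain lists and the counts over other splits of the arrays. Bootstrap intervals in this part were drawn over the genes of the lists, with the group means held fixed. They therefore leave out the spread between arrays, and genes of a list are not independent replicates. Genes of the secretory route were lower in vivo throughout. All 30 measured members of a list that left out genes already seen, covering entry into the endoplasmic reticulum, folding and transport to the Golgi, passed as lower in vivo, with a median of -1.86, against -0.0238 to 0.335 for the middle 95% of random lists of named genes of that size. The random lists were not matched for expression level, which these values do not hold. Ribosomal protein (median -1.16) and nuclear oxidative phosphorylation genes (-0.98) were lower too, so the comparison does not single out the secretory route. P4hb, a collagen-modifying disulfide isomerase (-3.39 ± 0.18 SE), Kdelr2, which returns escaped proteins (-3.31 ± 0.30), Ddost, a part of the glycosylation complex (-3.27 ± 0.26), and the folding enzyme Pdia3 (-3.02 ± 0.29) differed most, and were named after their values were seen. Why these genes were lower was not tested.

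Mitochondrially encoded genes went against their nuclear partners. All 5 measured genes were higher in vivo: ND6 by 3.31 ± 0.12, ND3 by 2.53 ± 0.39, ND2 by 1.07 ± 0.23, COX1 by 0.71 ± 0.073 and COX2 by 0.64 ± 0.068. Their median exceeded that of the nuclear respiratory chain genes by 2.05 (95% bootstrap interval over genes 1.15 to 4.29). Why they moved apart was not tested.

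Skeletal muscle genes had a median difference of 2.95 in vivo. A rise of dim clusters is argued against, since the middle 95% of random receptor lists of that size ended at 0.386. Muscle-like cells newly formed from skin cells were predicted to put developmental muscle genes at least 1 above the receptor genes, a bound set beforehand. The 8 developmental genes exceeded the receptor genes by 0.444 (95% bootstrap interval over genes 0.111 to 0.977). Of the 8, 7 passed as higher, among them Tnnt2 (1.43 ± 0.10), Myh8 (1.23 ± 0.12) and Myh3 (0.75 ± 0.059). Since probes may share transcripts of myosin heavy chain copies, the values of Myh8 and Myh3 are uncertain as to the copy. The prediction was not met, but the interval lies above 0, ends just under the bound and leaves out the spread between arrays. The test therefore does not decide whether such cells contributed. Adult muscle in the captured tissue, such as the thin muscle sheet under mouse skin, stays as a hypothesis, with adult genes 2.25 above developmental ones (1.52 to 3.49). How the captured regions were chosen is not given in the sources used here.

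Neuronal genes were higher in vivo by a median of 0.375 over 104 pooled genes. Rising receptor genes alone do not give this, since random receptor lists gave 0.216 to 0.307. Genes of organs outside skin, which skin hardly uses, had an increase of about that size: the neuronal median was -0.0657 relative to theirs (95% bootstrap interval -0.137 to 0.0524). So a general rise of little-used genes on these arrays may give the increase, and 1.92% of neuronal genes lay above 0.952, the upper end of the middle 95% of receptor genes. A biological difference between induced neurons in skin and in culture stays open.

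Over the 35 splits of the 7 arrays into 4 and 3, only the real split, 1 of 35, gave as many as 44422 clusters. That is the smallest share these splits can give, so chance is unlikely for that count but cannot be excluded. The highest other split gave 25572; it set in vitro replicates 1 to 3 against the rest, which points to the separate position of in vitro replicate 4. For the gene list tests 8 of the 35 splits gave at least the 19 lists of the real split, with 24 as the highest other value, so chance cannot be excluded for the number of lists.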
